A study of Mus musculus with 6 samples.

How the data were processed

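Immune cells of mouse tumours were profiled by single-cell RNA sequencing with the 10x Genomics 3' version 3 chemistry. A brain-metastatic breast cancer cell line had been injected either into the brain (BrM) or into the mammary fat pad (MFP) of female C57BL/6J mice. Each site has 3 libraries, so 6 libraries entered the comparison. Per the labels' protocols, tumours were digested enzymatically and stained for CD45 and CD11b, and cells positive for CD45 and for the nuclear stain RedDot1 and negative for the dead-cell stain DAPI were sorted. CD45 marks leukocytes and CD11b marks mainly myeloid cells; the stated gate did not use CD11b. Groups and replicate numbers came from the sample labels. The labels do not say that the 3 libraries of a site came from separate animals, so p-values measure only the spread between these samples, which may be technical.

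The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization. Per the submitters' processing notes they were made with Cell Ranger 4.0 on the mouse genome build mm10; the annotation release was not given in the sources used here. The authors' deposited barcode lists held 49518 barcodes already restricted to cells, each with at least 500 UMIs. All 6 feature lists held the same 32285 genes. No cell type annotation was used, because none was among the files analysed here. UMIs collapse PCR copies, so binomial intervals and limits for counts of 0 cover counting error of cells only.

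Cells were kept with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs, which removed 2627 barcodes. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 0.0367% of cells in BrM 3 and 0.0125% in MFP 1, too few to be usable, so the 7% of cells with the highest scores were removed in every library, 3283 cells in all; this rule was set after the scores were seen. The remaining 43608 cells were scaled to 10000 UMIs per cell and log-transformed. Clustering used 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at a resolution of 1.5 with seed 1, without integration of the libraries. Genes of proliferation, dissociation stress, mitochondria, ribosomes, immunoglobulin and T cell receptor segments and haemoglobin were left out of the variable genes. This gave 38 clusters, and 1 cluster of mixed T cells led by interferon genes was divided into 11 parts.

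Clusters were named from marker lists of 18 classes fixed before the data were examined. A name needed a marker score of at least 1 and at least 3 detected markers at 20 CPM or more, with a pseudocount of 5 CPM. The cDC2-like name also needed Flt3 at 20 CPM or more. A name was withdrawn where depth was low and no marker of the class was among the 10 leading genes. This left cluster 27 unnamed, at a score of 2.26, 9 detected markers and a depth of 0.333 times the library median. The thresholds were set after the clusters were seen. T cell clusters (CD3 genes at 100 CPM or more) were divided by Foxp3 (100 CPM), Trdc (1000 CPM), Cd8 genes (150 CPM) and Cd4 (80 CPM). T cell clusters with Fcer1g at 400 CPM or more were kept apart without a class name. So was a cluster with CD3 genes and type 2 cytokine genes, which scored high for the ILC2-like class (group 2 innate lymphoid cells). In this order they held a mean of 9.77% and 0.200% of BrM cells and 14.7% and 2.81% of MFP cells. The plan had been to test the macrophage-like class as a whole. After the clusters were seen, the macrophage-like clusters were compared by cluster number instead. The reason was that the top genes of the largest one, cluster 02, held a marker of another class and none of its own. In total 43440 cells entered a class or a numbered immune cluster; 168 cells of a non-immune cluster were left out. Names such as NK-like rest on expressed genes only.

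Raw counts were summed per library and class, and libraries with under 20 cells of a class were left out of its test. BrM was compared with MFP per class by the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM scaling and the filterByExpr filter, without covariates. All p-values per gene were adjusted by the Benjamini-Hochberg method at a threshold of 0.05, and log2 fold changes are BrM over MFP. Levels are in UMIs per 1000000 UMIs (CPM), as mean ± SD over libraries. Numbers of cells per class were tested by edgeR with the total of classified cells as library size, with the exact two-sided permutation test of shares beside it; with 3 libraries against 3, the latter cannot go below p = 0.1. Microglia-like cells, whose marker genes belong to 1 tissue, were reported as values.

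The 28 gene lists fixed before the data were examined cover the interferon response, the interferon-gamma response, MHC class I and class II presentation, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, NF-kB inflammation, proliferation, dissociation stress, the glucocorticoid response, the TGF-beta response, inhibitory receptors, cytotoxicity, naive and memory T cells, tissue residency, homing receptors, Treg activation, lipid-associated macrophages, matrix and wound healing, complement, myeloid chemokines, checkpoint ligands, connective tissue-resident macrophages, neutrophil granules, tumour neutrophils, mature dendritic cells and B cell activation. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists of a class, with an estimated correlation and with fry beside it. A list was called at the preset correlation; with an estimated correlation 0 of the 71 calls held, 11 of them had an unadjusted camera p under 0.05, and fry kept 1. Another 9 lists held markers of neurons, astrocytes, oligodendrocytes, mammary epithelium, fibroblasts, adipocytes, endothelium, erythroid cells and platelets. List levels per library are mean log2(CPM + 1) over measured members, compared by the exact permutation test.

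Named genes followed a rule fixed before the data were examined. They had an adjusted p under 0.05, no overlap between the libraries of the sites, at least 50 CPM at the higher site and at least 1/10 of the highest level in any other named class. Predicted gene models and mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes were left out. The 10 largest rises and 10 largest falls were named in the tested classes with the most cells and the 4 and 4 largest in the others. Up to 4 members per described list, those with the smallest p, were added without the limit of 1/10. Of these, Rsad2 and Ifit3 in NK-like, Oasl2 and Fos in CD4, Fos in Treg-like, Gbp2 in B-like, Tnf in monocyte-like and Ifit1 and Egr1 in cDC2-like cells and Cd9 in macrophage cluster 02 lay below it, and free RNA was not excluded for them. Hspa8, Hsp90aa1, Hsph1, Nfkbid, Ccr7, Il12b, Fscn1, Epcam, Wfdc18 and Sparcl1 were named after their values were seen. Coordinates come from GENCODE vM21 on GRCm38, the assembly called mm10, matched by gene identifier for 73 of 73 genes.

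The tests were checked on counts simulated from the real means, library sizes and dispersions with 200 genes changed. Genes changed by a log2 of 2 were recovered in 87% of cases in NK-like cells, 92% in CD4, 91% in CD8, 95% in Treg-like, 96% in B-like, 94% in monocyte-like, 70% in cDC2-like cells and 96% in macrophage cluster 02. For a log2 of 1 these values were 65%, 51%, 54%, 52%, 45%, 49%, 11% and 73%. False calls numbered 43 of 212 in macrophage cluster 02, 18 of 170 in NK-like, 10 of 153 in CD4, 9 of 154 in CD8, 10 of 157 in Treg-like, 12 of 153 in B-like, 14 of 157 in monocyte-like and 10 of 91 in cDC2-like cells, each above the 5% aimed at, and 6 of 154 in Fcer1g-high T cells.

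Alternatives fixed before the data were examined were DESeq2 1.42.0, library totals without TMM, a filter on all-zero genes only, doublets kept, counts thinned to the smallest library, cells classed singly, leaving out each library, the replicate number as a block and, for shares, other totals, resolutions of 1.5 and 0.67 times the main one and a stricter filter (1000 UMIs, 500 genes, 5% mitochondrial UMIs). Alternatives added after the data were seen concern library kind, defined by UMI totals. The submitters' library numbers separate the same libraries, so library kind may stand for a sorting or sequencing run, which the labels do not state. The 3 libraries with the lowest totals (BrM 1, MFP 1 and MFP 2) were set against the other 3, as a term in the model and each kind alone; each kind alone leaves 1 library at one site, which is assumed to vary like the others. Further added alternatives were lymphoid or myeloid cells as the total and named classes only. As stated above, all macrophage-like clusters together had been the planned class. Tables were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9.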

Results

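Leukocytes were isolated from tumours that grew in the brain (BrM) or in the mammary fat pad (MFP) after injection of the same breast cancer cell line, which had been derived from brain metastases. The comparison asks how the immune cells of a tumour differ between an intracranial and an extracranial site. Each site had 3 libraries. The BrM libraries 1 to 3 held 8252, 8185 and 8632 barcodes with 51152610, 70944735 and 60699618 UMIs. For MFP 1 to 3 the barcodes numbered 8380, 8986 and 7083, with 54976396, 50692794 and 70857349 UMIs. After filtering, 7375, 7147 and 7612 BrM cells and 7423, 7892 and 6159 MFP cells were analysed. The median depth per cell was 5345, 7839 and 5820 UMIs in BrM and 5435, 4919 and 7701 UMIs in MFP. The 3 libraries with the lowest UMI totals were BrM 1, MFP 1 and MFP 2, so that both sites contained libraries of lower and of higher total.

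T cells, NK cells and B cells were recovered from all 6 libraries, whereas macrophages, neutrophils and dendritic cells were frequent in only 3 of them. Lymphoid cells made up 96.3% of classified cells in BrM 1, 97.2% in MFP 1 and 99.0% in MFP 2. They made up 43.6% in BrM 2, 48.4% in BrM 3 and 30.1% in MFP 3, where macrophage-like cells reached 26.4%, 22.3% and 33.2%. In the lymphoid-rich libraries macrophage-like cells were 0.638%, 0.810% and 0.330%. The lymphoid-rich libraries were also those with the lowest UMI totals. Shares of all cells therefore varied more within a site than between the sites. The sort took CD45-positive cells, so the shares describe the sorted cells of each library.

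**Figure D1:**
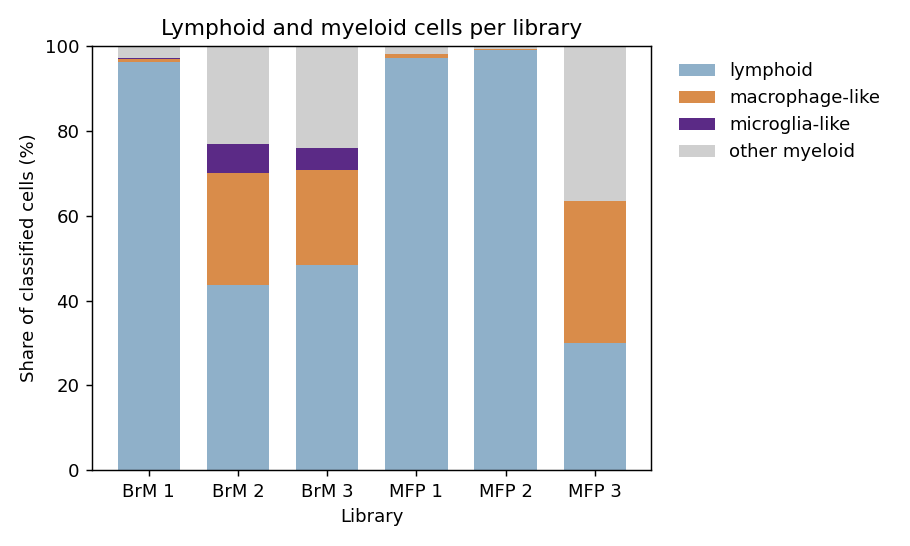
Share of classified cells (y axis, percent) in each of the 6 libraries (x axis), stacked as lymphoid, macrophage-like, microglia-like and other myeloid cells. Lymphoid cells fill over 96% of BrM 1, MFP 1 and MFP 2, and 30.1% to 48.4% of the others, while microglia-like cells are visible in BrM 2 (6.87%) and BrM 3 (5.15%).

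Microglia, the resident macrophages of the brain, were found almost exclusively in brain tumours. Microglia-like cells numbered 11 in BrM 1, 486 in BrM 2 and 391 in BrM 3. As shares of classified cells these were 0.149% (95% exact binomial interval 0.0746 to 0.267), 6.87% (6.29 to 7.48) and 5.15% (4.66 to 5.67). Among MFP cells, 1 cell of MFP 1 (0.0135%) had this class, and MFP 2 and MFP 3 had 0, which allows shares of up to 0.0381% and 0.0490%. MFP 1 and MFP 2 held only 209 and 76 myeloid cells, so MFP 3, with 4277, carries most of the comparison. Cluster 24, led by Sparc, P2ry12 and Fcrls, held 76.3% and 70.6% of the class in BrM 2 and BrM 3, while all 11 cells of BrM 1 and the cell of MFP 1 lay in cluster 34, whose 10 leading genes held no marker of the class. All 3 BrM libraries lay above all 3 MFP libraries (exact two-sided permutation p = 0.1, the smallest possible). For BrM 1 this rests on cluster 34, since cluster 24 held 0 cells of BrM 1 and 0 of each MFP library.

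Among lymphoid cells, gamma-delta T-like cells were more frequent in BrM. This class expressed Trdc, Cd163l1, Tcrg-C1 and Il17a, genes of the interleukin-17-producing gamma-delta lineage. It made up 10.0%, 4.50% and 3.83% of lymphoid cells in BrM 1 to 3 and 1.72%, 2.54% and 0.923% in MFP 1 to 3. With lymphoid cells as the total, a choice made after the data were seen, the difference passed the edgeR test (log2 fold change 1.81, SE 0.60), and with library kind as a term it was 2.21 (SE 0.29). As a share of all cells it was 9.68%, 1.96% and 1.86% against 1.67%, 2.51% and 0.278%, and this did not pass (log2 fold change 1.59, SE 1.27, edgeR adjusted p = 0.648; exact permutation p = 0.4).

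With all classified cells as the total, edgeR called 0 of 21 classes and clusters, with 0 at an unadjusted p under 0.05 (lowest 0.0611), and no exact permutation p was below 0.1. Mean shares were 16.2% ± 14.6 (SD, n = 3) in BrM and 29.4% ± 20.5 in MFP for NK-like cells, 14.5% ± 8.81 and 11.5% ± 6.50 for CD4 conventional T-like cells, and 12.1% ± 3.30 and 10.6% ± 5.45 for CD8 T-like cells. Treg-like cells were at 3.00% ± 1.27 and 2.64% ± 0.259, and B-like cells at 2.54% ± 2.75 and 2.24% ± 1.20. Dendritic classes had higher means in BrM, at 1.78% ± 1.20 against 0.246% ± 0.259 for cDC1-like cells (cross-presenting dendritic cells) and 4.50% ± 2.87 against 1.06% ± 1.23 for cDC2-like cells. Plasmacytoid DC-like cells were at 1.37% ± 1.08 and 0.190% ± 0.251. Neutrophil-like cells were found only in BrM 2 (3.81%), BrM 3 (4.09%) and MFP 3 (12.7%). With library kind as a term, chosen after the data were seen, 12 classes passed, 6 higher in each site. Those higher in BrM were cDC1-like (log2 fold change 2.15), cDC2-like (1.52), plasmacytoid DC-like (2.15), mature DC-like (2.40) and gamma-delta T-like cells (2.46) and macrophage cluster 16 (3.65), which was led by Apoc2, Gpnmb, Spp1 and Trem2, genes of lipid-laden macrophages. Those lower were neutrophil-like cells (-1.66), the type 2 cytokine cluster (-2.05), macrophage clusters 25 (-1.64) and 30 (-5.07) and the unnamed clusters 27 (-4.32) and 36 (-9.50). Neutrophil-like and mature DC-like cells numbered 0 in BrM 1, MFP 1 and MFP 2, so their contrast is BrM 2 and BrM 3 with MFP 3 alone, and clusters 16, 25, 27, 30 and 36 held at most 6 cells in each of those 3 libraries.

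The interferon response list, antiviral genes induced mainly by type I interferon, was called higher in BrM in NK-like, CD4 T-like, CD8 T-like, B-like, monocyte-like and cDC2-like cells, but it was not called in Treg-like cells or in macrophage cluster 02. No call held with an estimated correlation, where the adjusted p = 0.271, 0.307, 0.732, 0.469, 0.179 and 0.931 in the same order. Median log2 fold changes over the measured members were 0.45 in NK-like, 0.43 in CD4, 0.31 in CD8, 0.69 in B-like, 0.55 in monocyte-like and 0.21 in cDC2-like cells. In Treg-like cells the median was 0.01 (camera adjusted p = 0.900), and in macrophage cluster 02 it was 0.29 (camera adjusted p = 0.0929), although 3 of its 25 measured members rose there. In macrophage cluster 02 it was called, with a median of 0.35, within the libraries of higher total, where MFP 3 stands alone for its site. Differences between classes were not tested. As a level per library, the list was at 5.23 ± 0.07 (mean log2(CPM + 1), SD, n = 3) in BrM and 4.88 ± 0.19 in MFP for NK-like cells, 6.22 ± 0.04 and 5.85 ± 0.15 for CD4, and 7.97 ± 0.23 and 7.33 ± 0.36 for monocyte-like cells. In these classes the sites did not overlap (exact permutation p = 0.1 each). They overlapped for CD8 (5.95 ± 0.26 and 5.64 ± 0.23, exact p = 0.3), B-like (6.17 ± 0.55 and 5.55 ± 0.39, exact p = 0.2), cDC2-like (6.96 ± 0.34 and 6.68 ± 0.25, exact p = 0.4) and Treg-like cells (5.95 ± 0.37 and 6.00 ± 0.51, exact p = 0.9). In macrophage cluster 02 they overlapped too, and the difference in mean level was -0.21, of the opposite sign to the median (5.50 ± 0.18 and 5.71 ± 0.60, n = 2, exact p = 1). Within the libraries of lower and of higher UMI total, the medians were 0.34 and 0.31 in NK-like, 0.46 and 0.54 in CD4, 0.59 and 0.03 in CD8, 0.14 and 0.81 in B-like and 0.33 and 0.52 in monocyte-like cells. In Treg-like cells they were 0.35 and -0.39. Over all lists in the 6 named classes with 6 libraries, 20 of 103 list levels did not overlap between the sites (19.4%, against 10% from chance), 8 of them higher in BrM and 12 in MFP; in the unnamed Fcer1g-high T clusters 3 of 17 did not, all higher in MFP.

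**Figure D2:**
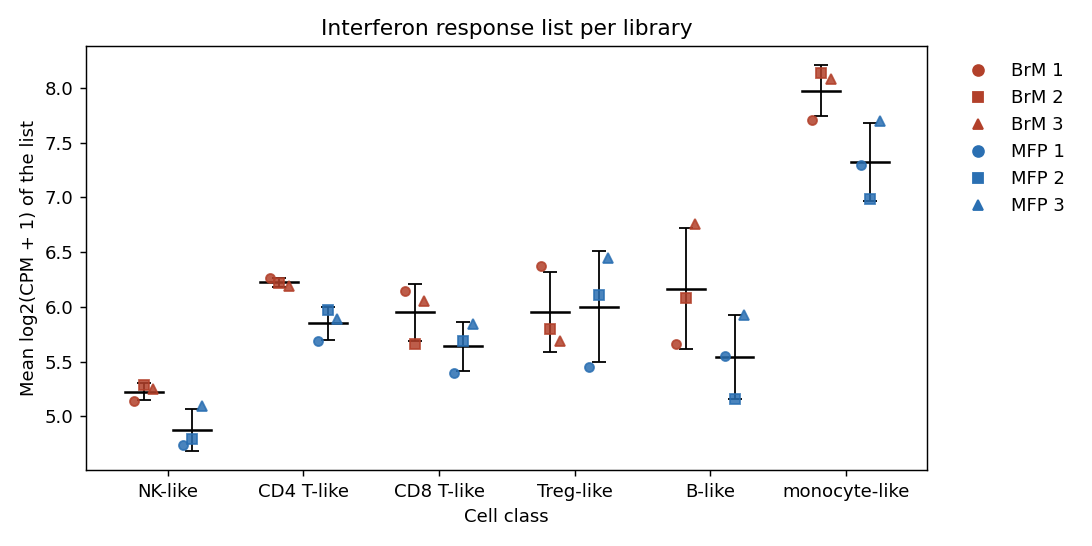
Level of the interferon response list, mean log2(CPM + 1) over its measured members (y axis), in 6 cell classes (x axis); each symbol is 1 library, lines are means and bars are SD (n = 3). BrM libraries lie above MFP libraries in NK-like, CD4 T-like and monocyte-like cells, at 5.23 against 4.88, 6.22 against 5.85 and 7.97 against 7.33, and the sites overlap in the other classes, Treg-like cells among them (5.95 against 6.00).

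In NK-like cells the interferon response list was called higher in BrM. Of its 25 genes, 9 rose adjusted over the list alone and none over all genes tested (camera adjusted p = 1.71e-11; adjusted p = 0.271 with an estimated correlation). Rsad2, an antiviral enzyme, had a log2 fold change of 0.91 and Ifit3 one of 0.71, but they lay at only 0.0189 and 0.0316 times their highest level in another class, and free RNA was not excluded for either gene. In the interferon-gamma list 3 of 21 genes rose adjusted over the list alone (camera adjusted p = 0.000261; adjusted p = 0.271 with an estimated correlation). Its member Igtp, an interferon-inducible GTPase, was at 103 ± 12.9 CPM in BrM and 55.3 ± 2.87 CPM in MFP (n = 3; edgeR adjusted p = 0.114). All 25 proliferation genes had a positive log2 fold change, with a median of 1.13, but none passed adjusted over the list alone (camera adjusted p = 1.31e-06; adjusted p = 0.565 with an estimated correlation). Their median fell to 0.22 with library kind as a term, and was -0.34 among the libraries of lower UMI total and 0.98 among the others. Cholesterol synthesis genes had a median of 0.33 (18 measured, none passing adjusted over the list alone; camera adjusted p = 0.000261; adjusted p = 0.560 with an estimated correlation). Homing receptors had a median of -0.26 (13 measured, none passing adjusted over the list alone; camera adjusted p = 0.000261; adjusted p = 0.458 with an estimated correlation). Their levels overlapped between the sites (6.64 ± 0.27 and 6.99 ± 0.10, exact permutation p = 0.2). Among them, the chemokine receptor Ccr2 had a log2 fold change of -0.36 and the integrin Itgb2 one of -0.32. The NK-like cluster 00 held 40.6%, 50.1% and 49.3% of the class in BrM and 28.2%, 34.0% and 27.2% in MFP.

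In NK-like cells (3577 in BrM and 6600 in MFP, 2453622 to 18828042 UMIs per library), edgeR called 0 of 10729 genes, with 1026 at an unadjusted p under 0.05, and DESeq2 called 40. A term for library kind gave 9 genes, and 731 and 394 passed within the libraries of lower and higher total. Without BrM 1 there were 875 genes and 8 lists, and without MFP 3 there were 9 lists, against 5 lists with all libraries.

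CD4 conventional T-like cells of BrM had less of the immediate-early transcription factor Fosb than those of MFP. Fosb (ENSMUSG00000003545, protein-coding, GRCm38 chromosome 7, 19302696 to 19310051, minus strand) was at 73.6 ± 17.2 CPM in BrM and 242 ± 22.02 CPM in MFP (SD, n = 3). It was the only gene called (log2 fold change -1.62, SE 0.17, edgeR adjusted p = 0.0379), lower in all 3 BrM libraries than in any MFP library. Its partner Fos was at 116 ± 26.0 and 273 ± 22.3 CPM (adjusted p = 0.0952). In the dissociation stress list, which holds both, 1 of 20 genes fell over all genes tested, and adjusted over the list alone 8 fell and 1, the chaperone Hspa8 (log2 fold change 0.39), rose (camera adjusted p = 1.71e-05; adjusted p = 0.307 with an estimated correlation). Inhibitory receptors and their companions had a median of -0.53, and 5 of 20 fell adjusted over the list alone (camera adjusted p = 1.97e-06; adjusted p = 0.319 with an estimated correlation). The G-protein regulator Rgs16 was at 144 CPM in BrM and 371 CPM in MFP, and the inhibitory receptor Lag3 had a log2 fold change of -0.96. Of 15 tissue-residency genes 4 fell adjusted over the list alone (median -0.29, camera adjusted p = 3.17e-05; adjusted p = 0.159 with an estimated correlation). Itgae, the CD103 integrin that binds E-cadherin, had a log2 fold change of -0.85, the aryl hydrocarbon receptor Ahr one of -0.79 and the phosphatase Dusp6 one of -1.09.

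Of the TGF-beta response genes in CD4 T-like cells, 3 of 12 fell adjusted over the list alone (camera adjusted p = 0.000498; adjusted p = 0.319 with an estimated correlation), as did 1 of 16 Treg activation genes (camera adjusted p = 0.0134; adjusted p = 0.358 with an estimated correlation). In the interferon response list 10 of 25 genes rose adjusted over the list alone (camera adjusted p = 1.46e-11; adjusted p = 0.307 with an estimated correlation), with Oasl2 at a log2 fold change of 0.98 and Ifi209 at 0.70. The interferon-gamma list had 3 of 20 rising adjusted over the list alone (camera adjusted p = 0.000114; adjusted p = 0.307 with an estimated correlation), and Igtp had a log2 fold change of 0.82. Proliferation genes had a median of 1.44, and 14 of 25 rose adjusted over the list alone (camera adjusted p = 1.00e-19; adjusted p = 0.307 with an estimated correlation). They included the replication helicase subunit Mcm7 (1.12) and the chromatin protein Hmgb2 (1.03). Their median was 0.50 within the libraries of lower total and 1.38 within the others. Oxidative phosphorylation genes were positive in 30 of 31 cases with a median of 0.24, none passing adjusted over the list alone (camera adjusted p = 5.08e-06; adjusted p = 0.389 with an estimated correlation). The share of cluster 06, led by Penk, Tff1 and Ccl1, overlapped between the sites at 12.1%, 31.3% and 39.0% of the class in BrM and 43.3%, 33.6% and 47.7% in MFP, as did that of a cluster led by Ifit1 at 0.112%, 11.2% and 11.6% against 1.22%, 0.449% and 2.65%.

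The CD4 test covered 3205 BrM and 2582 MFP cells (1577232 to 10892214 UMIs per library) and 10272 genes, of which 1848 had an unadjusted p under 0.05. DESeq2 called 242 genes, 171 higher and 71 lower in BrM. The model with library kind gave 240 (74 higher, 166 lower), and 1292 and 1477 passed within the libraries of lower and higher total. Without 1 library the edgeR count ran from 0 to 1711.

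Treg-like cells, which express Foxp3 and restrain other T cells, had lower immediate-early transcripts in BrM than in MFP. Fos (ENSMUSG00000021250, protein-coding, GRCm38 chromosome 12, 85473890 to 85477273, plus strand) was at 48.6 ± 1.24 CPM in BrM and 181 ± 31.6 CPM in MFP (SD, n = 3; log2 fold change -1.83, SE 0.19, edgeR adjusted p = 0.000226). Fosb fell from 144 ± 21.3 CPM in MFP to 39.99 ± 9.93 CPM in BrM (-1.80, SE 0.22, adjusted p = 0.000451), and Zfp36, which destabilises cytokine mRNAs, from 238 ± 13.6 to 92.7 ± 26.4 CPM (-1.29, SE 0.20, adjusted p = 0.00717). Rgs16 (ENSMUSG00000026475, protein-coding, GRCm38 chromosome 1, 153740349 to 153745468, plus strand), which curbs chemokine receptor signalling, was at 119.6 ± 19.0 CPM in BrM and 368 ± 8.45 CPM in MFP (-1.56, SE 0.18, adjusted p = 0.000411). The scaffold gene Ahnak fell likewise (-1.38, SE 0.21, adjusted p = 0.00717). Ppid, a cyclophilin that works with the Hsp90 chaperone, was the only gene that rose, at 104 ± 30.8 against 41.0 ± 6.41 CPM (1.34, SE 0.24, adjusted p = 0.0414). It did not pass with library kind as a term (1.25, SE 0.28).

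**Figure D3:**
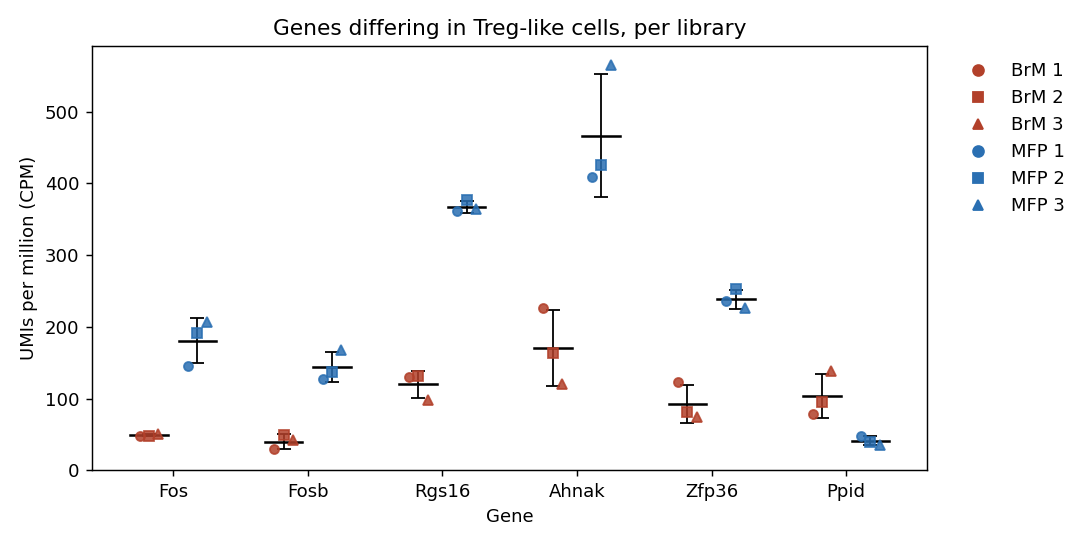
CPM, UMIs per 1000000 UMIs (y axis, linear) of 6 genes (x axis) in Treg-like cells; each symbol is 1 library, lines are means and bars are SD (n = 3). Fos (48.6 against 181 CPM), Fosb, Rgs16 (119.6 against 368 CPM), Ahnak and Zfp36 are lower in every BrM than in every MFP library, and Ppid is higher (104 against 41.0 CPM).

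Of 20 dissociation stress genes in Treg-like cells, 3 fell (Fos, Fosb and Zfp36) and 17 did not pass. Adjusted over the list alone 11 fell and 3 rose (camera adjusted p = 8.07e-05; adjusted p = 0.220 with an estimated correlation); those that rose were the chaperones Hsp90aa1 (log2 fold change 0.66), Hspa8 (0.50) and Hsph1 (0.69). In the NF-kB list 1 of 16 genes fell, Nfkbid, and 5 fell adjusted over the list alone (camera adjusted p = 0.00182; adjusted p = 0.266 with an estimated correlation). Of 18 Treg activation genes 5 fell adjusted over the list alone (camera adjusted p = 0.000779; adjusted p = 0.365 with an estimated correlation), and Areg, an epidermal growth factor-like repair factor, had a log2 fold change of -1.12. The residency list had 3 of 11 falling adjusted over the list alone (camera adjusted p = 0.000787; adjusted p = 0.220 with an estimated correlation), with Itgae at -0.84. Inhibitory receptors had 1 of 15 falling, Rgs16, and 3 adjusted over the list alone (camera adjusted p = 8.07e-05; adjusted p = 0.220 with an estimated correlation), and the activation-induced nuclear receptor Nr4a3 had a log2 fold change of -1.14. Cytotoxicity genes had 5 of 14 falling adjusted over the list alone (camera adjusted p = 0.000810; adjusted p = 0.220 with an estimated correlation), with the death ligand Fasl at -1.53. All 12 TGF-beta response genes were negative and 5 fell adjusted over the list alone (camera adjusted p = 7.74e-05; adjusted p = 0.220 with an estimated correlation). Glucocorticoid response genes had 4 of 9 falling (camera adjusted p = 0.000787) and homing receptors 1 of 15 rising and 1 falling (camera adjusted p = 0.00823), both adjusted over the list alone and both at adjusted p = 0.266 with an estimated correlation.

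Proliferation genes in Treg-like cells had a median of 0.97, and 9 of 25 rose adjusted over the list alone and none over all genes tested (camera adjusted p = 6.07e-13; adjusted p = 0.266 with an estimated correlation). Their levels overlapped between the sites (7.14 ± 0.43 and 6.02 ± 0.82, exact permutation p = 0.2). The thymidylate synthase gene Tyms had a log2 fold change of 1.43 and the replication clamp gene Pcna one of 0.83. Their median was 0.50 within the libraries of lower total and 1.38 within the others. Oxidative phosphorylation genes had a median of 0.26, with 1 of 31 rising adjusted over the list alone (camera adjusted p = 7.74e-05; adjusted p = 0.478 with an estimated correlation), and cholesterol synthesis genes a median of 0.07, with 2 of 14 rising adjusted over the list alone (camera adjusted p = 0.0370; adjusted p = 0.494 with an estimated correlation). In all, edgeR called 11 of 7827 genes, 1 higher and 10 lower in BrM, from 657 BrM and 568 MFP cells (708281 to 2562722 UMIs per library). With library kind as a term 7 genes passed, all of them lower in BrM and among the 11, and 1 and 1051 passed within the libraries of lower and higher total. DESeq2 called 252 genes with another balance, 158 higher and 94 lower. Without 1 library the count ran from 4 to 708.

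In CD8 T-like cells the interferon response list was called higher in BrM, with no single gene past the threshold. Its levels overlapped (exact permutation p = 0.3). Its median was 0.03 within the libraries of higher total and larger within the others. All 25 genes were positive, none passing adjusted over the list alone (camera adjusted p = 1.23e-10; adjusted p = 0.732 with an estimated correlation). Usp18, which removes the ubiquitin-like ISG15 from proteins, had a log2 fold change of 0.67 (SE 0.18) and the DNA-sensing family member Ifi209 one of 0.54. Interferon-gamma genes had a median of 0.27 (camera adjusted p = 0.00178; adjusted p = 0.732 with an estimated correlation), with none of 20 passing adjusted over the list alone; the median was 0.67 within the libraries of lower total and 0.03 within the others. The 22 genes of hypoxia and glycolysis had a median of -0.25, and none passed adjusted over the list alone (camera adjusted p = 8.37e-06; adjusted p = 0.732 with an estimated correlation); it was -0.55 within the libraries of lower total and 0.08 within the others. The glycolytic Gapdh had a log2 fold change of -0.52 and the collagen hydroxylase P4ha1 one of -0.41. Inhibitory receptors had a median of -0.26, none of 20 passing adjusted over the list alone (camera adjusted p = 0.0329; adjusted p = 0.732 with an estimated correlation). Their median was -1.03 within the libraries of lower total and 0.68 within the others, and the list was not called with library kind as a term. In the residency list 1 of 16 genes fell adjusted over the list alone (camera adjusted p = 0.0329; adjusted p = 0.732 with an estimated correlation), but the median was -0.60 and 0.23 in the 2 kinds of library and the call was lost with library kind as a term. All 25 proliferation genes were positive, none passing adjusted over the list alone (camera adjusted p = 0.0170; adjusted p = 0.806 with an estimated correlation), but their median turned to -0.10 with library kind as a term and to -0.71 within the libraries of lower total. Cluster 19, led by Pdcd1 and Lag3, held 1.58%, 34.3% and 7.63% of the class in BrM and 22.5%, 16.8% and 9.39% in MFP.

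From 2663 BrM and 2370 MFP CD8 T-like cells (2830708 to 9347365 UMIs per library), edgeR called 0 of 10309 genes, with 503 at an unadjusted p under 0.05, and DESeq2 called 7. With library kind as a term edgeR called 0, and 961 and 2 passed within the libraries of lower and higher total. Without BrM 2 there were 10 called lists, against 6 with all libraries.

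B-like cells of BrM showed a higher interferon response list. All 13 measured interferon response genes were positive (camera adjusted p = 4.09e-05; adjusted p = 0.469 with an estimated correlation), with none passing adjusted over the list alone. In the interferon-gamma list 1 of 14 genes rose adjusted over the list alone (camera adjusted p = 0.000151; adjusted p = 0.469 with an estimated correlation), with the guanylate-binding protein gene Gbp2 at a log2 fold change of 2.25 (SE 0.52), at 0.0444 times its highest level in another class; free RNA was not estimated in B-like cells. The median of this list, 0.79, became 0.39 with library kind as a term, and was -0.12 within the libraries of lower total and 1.25 within the others. Of 17 MHC class I genes 16 were positive, none passing adjusted over the list alone (camera adjusted p = 0.000308; adjusted p = 0.469 with an estimated correlation), while the MHC class II list was not called (median 0.03, camera adjusted p = 0.545). The MHC class I median was -0.14 within the libraries of lower total and 0.71 within the others. The checkpoint ligand list had 4 measured members, of which 1 rose adjusted over the list alone (camera adjusted p = 0.0123; adjusted p = 0.469 with an estimated correlation); this call was lost with library kind as a term, as was that of oxidative phosphorylation. Of its members, the costimulatory ligand Cd86 was at 257 CPM in BrM and 119.8 CPM in MFP. Hypoxia and glycolysis genes had a median of 0.31 (16 measured, camera adjusted p = 0.0104), with the lactate dehydrogenase gene Ldha at 0.66, and stress genes one of -0.31 (20 measured, camera adjusted p = 0.00418), none passing adjusted over the list alone and both at adjusted p = 0.469 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.15 (31 measured, none passing adjusted over the list alone; camera adjusted p = 0.0123; adjusted p = 0.604 with an estimated correlation). B cell activation genes had a median of -0.28 and were not called (camera adjusted p = 0.291).

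From 562 BrM and 502 MFP B-like cells (180078 to 1507092 UMIs per library), edgeR called 0 of 5204 genes, with 347 at an unadjusted p under 0.05, and DESeq2 called 0. A library kind term gave 2, and 50 and 105 passed within the libraries of lower and higher total. Without BrM 1 there were 374 genes, and without BrM 3 there were 2 called lists, against 7 with all libraries.

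Monocyte-like cells, the blood-derived precursors of tumour macrophages, had higher Isg15, Isg20, Tnf and Nfkbia in BrM and lower Clec4b1, Tppp3 and Mmp19. The class held clusters 17 and 20 in proportions that differed between the sites. A change in this mix was not separated from a change within cells. Isg15 (ENSMUSG00000035692, protein-coding, GRCm38 chromosome 4, 156199424 to 156200818, minus strand), a ubiquitin-like antiviral protein, was at 1371 ± 115 CPM in BrM and 805 ± 71.9 CPM in MFP (SD, n = 3; log2 fold change 0.85, SE 0.15, edgeR adjusted p = 0.0277). The exonuclease gene Isg20 was at 201 ± 13.6 and 92.7 ± 10.2 CPM (1.24, SE 0.17, adjusted p = 0.00641). The inflammatory cytokine Tnf rose from 106 ± 22.6 to 227 ± 50.5 CPM (1.15, SE 0.21, adjusted p = 0.0311) and the NF-kB inhibitor Nfkbia from 827 ± 105 to 1372 ± 139 CPM (0.80, SE 0.15, adjusted p = 0.0363). The nuclear lamina gene Lmnb1 (1.37, SE 0.21, adjusted p = 0.0172), the arginase gene Arg2 (1.29) and Smim3 (1.13) rose too. Clec4b1 (ENSMUSG00000030147, protein-coding, GRCm38 chromosome 6, 123049962 to 123071555, plus strand), a C-type lectin receptor gene, was at 16.2 ± 4.03 CPM in BrM and 81.9 ± 13.3 CPM in MFP (-2.21, SE 0.21, adjusted p = 0.000512). Tppp3 fell by 1.86 on the log2 scale, the matrix metalloproteinase gene Mmp19 by 1.77 and Batf3, a transcription factor of dendritic cells, by 1.30. Fosb fell here as well, from 413 to 169.9 CPM (-1.19, SE 0.22, adjusted p = 0.0422).

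**Figure D4:**
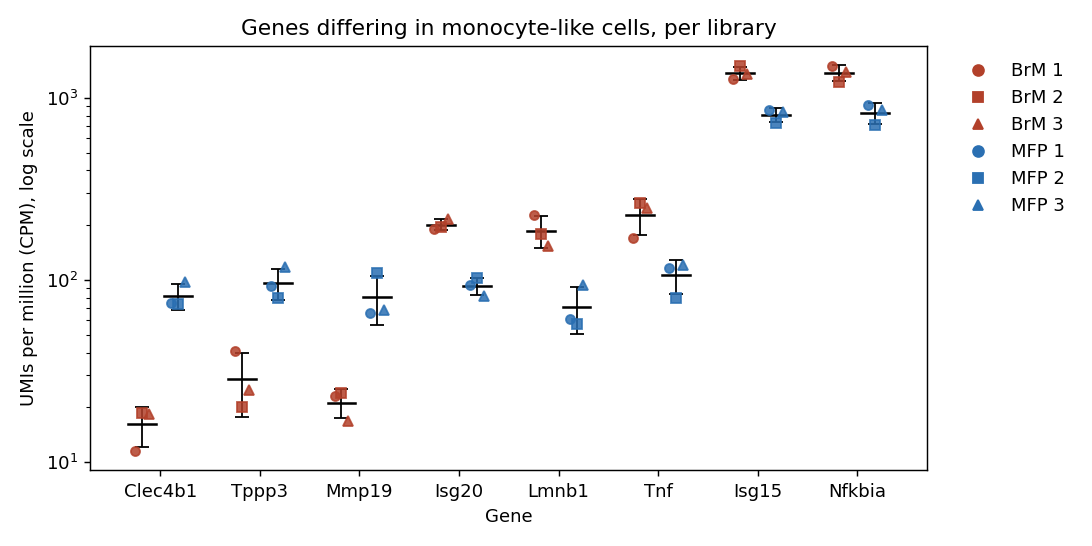
CPM, UMIs per 1000000 UMIs (y axis, log scale) of 8 genes (x axis) in monocyte-like cells; each symbol is 1 library, lines are means and bars are SD (n = 3). Clec4b1 (16.2 against 81.9 CPM), Tppp3 and Mmp19 are lower in every BrM than in every MFP library, and Isg20 (201 against 92.7 CPM), Lmnb1, Tnf, Isg15 and Nfkbia are higher.

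Of 25 interferon response genes in monocyte-like cells 1, Isg15, rose and 24 did not pass, and 8 rose adjusted over the list alone (camera adjusted p = 1.65e-08; adjusted p = 0.179 with an estimated correlation). In the interferon-gamma list 1 of 21 rose adjusted over the list alone (camera adjusted p = 0.000931; adjusted p = 0.437 with an estimated correlation), and the chemokine Cxcl10, which attracts activated T cells, was at 2718 CPM in BrM and 1399 CPM in MFP. Of 21 NF-kB genes 2 rose, Tnf and Nfkbia, and the same number adjusted over the list alone (camera adjusted p = 0.000662; adjusted p = 0.337 with an estimated correlation). Checkpoint ligands had 5 of 13 rising and 1 falling adjusted over the list alone (camera adjusted p = 0.000285; adjusted p = 0.221 with an estimated correlation), with the PD-1 ligand Cd274 at a log2 fold change of 0.88 and the interleukin-1 antagonist Il1rn at 0.78. Myeloid chemokines had 2 of 13 rising adjusted over the list alone (camera adjusted p = 0.000931; adjusted p = 0.221 with an estimated correlation). The tumour-neutrophil list had 2 of 14 rising and 3 adjusted over the list alone (camera adjusted p = 8.96e-05; adjusted p = 0.221 with an estimated correlation), and the mature dendritic list 1 of 8, Ccr7, and 3 adjusted over the list alone (camera adjusted p = 0.000864; adjusted p = 0.221 with an estimated correlation). The lipid-associated macrophage list had 6 of 20 rising adjusted over the list alone (camera adjusted p = 1.56e-05; adjusted p = 0.337 with an estimated correlation) and the TGF-beta list 3 of 11 (camera adjusted p = 0.00730; adjusted p = 0.337 with an estimated correlation). The connective tissue-resident macrophage list had a median of -0.98 with all 6 members negative (camera adjusted p = 0.0163; adjusted p = 0.337 with an estimated correlation), none passing adjusted over the list alone.

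In the other lists called in monocyte-like cells, MHC class I genes had a median of 0.20 (18 measured, camera adjusted p = 0.00875; adjusted p = 0.369 with an estimated correlation) and proliferation genes one of 0.49 (15 measured, camera adjusted p = 0.00168; adjusted p = 0.451 with an estimated correlation), none passing adjusted over the list alone; the latter was -0.20 within the libraries of lower total. Hypoxia and glycolysis genes had 1 of 22 rising adjusted over the list alone (camera adjusted p = 0.0232; adjusted p = 0.435 with an estimated correlation). In the stress list 1 of 20 fell, Fosb, and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.0334; adjusted p = 0.437 with an estimated correlation). Cluster 20, led by Cxcl9, Cxcl10 and Ms4a4c, made up 44.6%, 67.3% and 69.2% of the class in BrM and 27.4%, 20% and 22.2% in MFP. Cluster 17, led by Chil3, Hp and Vcan and with Tppp3 among its 10 leading genes, made up the rest. Differences between the sites within each cluster were not tested. The epithelial genes Epcam (11.3 CPM in BrM and 2.35 CPM in MFP) and Wfdc18 (47.7 and 17.4 CPM) were also called higher.

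From 1038 BrM and 776 MFP monocyte-like cells (312434 to 6983185 UMIs per library), edgeR called 41 of 8286 genes, 22 higher and 19 lower in BrM. Without TMM 38 passed, 13 higher and 25 lower, and DESeq2 called 81, 53 higher and 28 lower. Adding library kind to the model gave 408, all 41 among them, and 94 and 1399 passed within the libraries of lower and higher total. Without 1 library the count ran from 1 to 259, and without BrM 3 there were 9 called lists, against 14.

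The largest macrophage-like cluster, cluster 02, was compared by its number. It was led by H2-M2, Vcam1, Dnase1l3 and Acp5, and its 10 leading genes held no marker of macrophages and 1 of cDC1-like cells, Cadm1. In BrM these cells had less of the glucocorticoid-induced Fkbp5, and the interferon-gamma and MHC class I lists were called higher (adjusted p = 0.668 with an estimated correlation for each), although the levels of both lists per library overlapped. The test held 2 libraries per site, and MFP 1 contributed 20 cells (195267 UMIs) beside the 17103983 UMIs of MFP 3. Ccl12 (ENSMUSG00000035352, protein-coding, GRCm38 chromosome 11, 82101845 to 82103400, plus strand), a ligand of Ccr2, was at 392 ± 127 CPM in BrM and 135 ± 48.1 CPM in MFP (SD, n = 2; log2 fold change 1.95, SE 0.25, edgeR adjusted p = 1.24e-05). Other large rises were the mitochondrial carrier Slc25a33 (1.20), the transcription factor Nfil3 (1.10), the costimulatory receptor Cd40 (1.09, SE 0.17), the apolipoprotein Apoc2 (1.09, SE 0.16), lipoprotein lipase Lpl (1.00, SE 0.16), complement factor Cfb (0.99) and Limd2 (0.95). For Cd40 and Nfil3, MFP 1 (61.5 and 71.7 CPM) lay nearer to BrM 2 (66.6 and 90.4 CPM) than MFP 3 did (38.8 and 46.1 CPM). Their fold changes therefore rest mainly on MFP 3. For Slc25a33, Apoc2, Lpl and Limd2, MFP 1 lay below MFP 3. Fkbp5 was at 12.3 ± 1.58 and 33.9 ± 11.7 CPM (-1.57, SE 0.19, adjusted p = 4.47e-07). Large falls outside the lists were the Wnt receptor Fzd7 (-1.32), the cytokine receptor Lifr (-1.27, SE 0.16), the mitochondrial leucyl-tRNA synthetase Lars2 (-1.24), urokinase Plau (-1.17, SE 0.22), Plk3 (-1.10), Pid1 (-0.98), Pou2f2 (-0.94), Pdgfb (-0.93), Myo1c (-0.93) and Fam189a2 (-0.93).

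Of 21 interferon-gamma genes in macrophage cluster 02, 6 rose and 15 did not pass, and 7 rose adjusted over the list alone (camera adjusted p = 0.00456; adjusted p = 0.668 with an estimated correlation). The GTPase genes Gbp2 (1.04, SE 0.20) and Irgm1 (1.01, SE 0.18) were among them. The level of the list was 6.03 and 6.57 (mean log2(CPM + 1)) in BrM 2 and BrM 3 and 6.64 and 5.66 in MFP 1 and MFP 3 (exact permutation p = 1). MHC class I genes were positive in all 18 cases, with 3 rising and 7 adjusted over the list alone (camera adjusted p = 8.27e-06; adjusted p = 0.668 with an estimated correlation), including the proteasome activator Psme2 (0.84). MHC class II genes had 2 of 12 rising and 3 adjusted over the list alone (median 0.34, camera adjusted p = 0.0401; adjusted p = 0.668 with an estimated correlation), a call lost with library kind as a term (median 0.08). The lipid-associated macrophage list had 4 of 19 rising, Cd9 (0.91) among them, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.000250; adjusted p = 0.668 with an estimated correlation). Cholesterol synthesis had 3 of 18 rising, with Fdps at 0.91, and 5 adjusted over the list alone (camera adjusted p = 0.00456; adjusted p = 0.668 with an estimated correlation). Oxidative phosphorylation had 2 of 31 rising, including Ndufa4 (0.84), and the same number adjusted over the list alone (camera adjusted p = 9.83e-09; adjusted p = 0.668 with an estimated correlation). In the mature dendritic list 4 of 12 rose, Cd40, Il12b, Ccr7 and Fscn1 (the last at 1.13 CPM in BrM), and 5 adjusted over the list alone (camera adjusted p = 0.000130; adjusted p = 0.668 with an estimated correlation). Of 11 glucocorticoid response genes 2 fell, Fkbp5 and the clock gene Per1 (-0.66), and adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.00456; adjusted p = 0.668 with an estimated correlation). TGF-beta response genes had 2 of 13 falling and 3 adjusted over the list alone (camera adjusted p = 0.0324; adjusted p = 0.668 with an estimated correlation).

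In macrophage cluster 02 (2213 BrM and 1062 MFP cells), edgeR called 715 of 11519 genes, 388 higher and 327 lower in BrM. DESeq2 called 11 genes. Without TMM 673 passed, 140 higher and 533 lower, with the median of all genes moved from -0.00 to -0.16 on the log2 scale. Only MFP 1 was of lower total, so a term for library kind, the libraries of higher total and leaving out MFP 1 are 1 contrast, of BrM 2 and BrM 3 with MFP 3 alone. It gave 1562 genes as a term, 669 of the 715 among them, and 1522 in the other 2 forms; Ccl12 (2.09, SE 0.45), Gbp2 (1.11, SE 0.29), Irgm1 (1.03, SE 0.24) and Plau (-1.03, SE 0.39) did not pass with the term. The count was 25 without BrM 2 and 10 without BrM 3, and 1522 without MFP 1. With counts thinned to the smallest library edgeR called 0, and with all macrophage-like clusters together, the planned class, 362.

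Type 2 conventional dendritic cells, which present antigen to CD4 T cells, were tested with no single gene past the threshold in edgeR, and 4 lists were called, none of which held (adjusted p = 0.931 with an estimated correlation for each). Egr1, an immediate-early transcription factor, was at 54.4 CPM in BrM and 154 CPM in MFP (log2 fold change -1.47, SE 0.26), and the phosphatase Dusp1 had a log2 fold change of -0.85 (SE 0.17). In the stress list, which holds both, 3 of 20 fell adjusted over the list alone (camera adjusted p = 0.000355). NF-kB genes had 4 of 19 falling adjusted over the list alone (camera adjusted p = 0.0207). The interferon response list had 1 of 25 rising adjusted over the list alone (camera adjusted p = 0.00141). Ifit1 was at 156 CPM in BrM and 55.3 CPM in MFP (1.43, SE 0.30). Connective tissue-resident macrophage genes had 2 of 7 falling adjusted over the list alone (camera adjusted p = 0.0416), with the lectin Mgl2 at -1.97. From 988 BrM cells of 3 libraries and 195 MFP cells of 2 libraries (482060 to 4817110 UMIs per library), edgeR called 0 of 9059 genes, with 581 at an unadjusted p under 0.05, and DESeq2 called 16. With library kind as a term 146 genes and 7 lists passed, and 100 genes and 11 lists within the libraries of higher total. There were 25 genes without BrM 1.

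Besides B cell activation, lists without a call in any class tested were naive and memory T cell genes (medians from -0.12 to 0.14, camera adjusted p of 0.155 or more), matrix and wound healing genes (camera adjusted p = 0.174 in macrophage cluster 02, 0.935 in monocyte-like and 0.344 in cDC2-like cells), complement genes (0.363, 0.409 and 0.861 in the same order) and neutrophil granule genes (0.318, 0.407 and 0.872). Among markers of other cell types, neuronal markers had at most 2 measured members per class and medians from -0.37 to 0.63, and oligodendrocyte markers at most 4 and medians from -0.30 to 0.09, with sums of 147 CPM in BrM and 163 CPM in MFP in CD4 cells. Endothelial markers had at most 3 members (medians -0.40 to 0.86) and platelet markers 1 (0.30 to 1.57). No fibroblast, adipocyte or erythroid marker entered a gene test, but haemoglobin genes led CD8 cluster 14. Astrocyte markers had at most 2 members and medians from -0.69 to 3.49, the highest in macrophage cluster 02, where Sparcl1 was called higher at 1.45 CPM in BrM and 0 in both MFP libraries. Mammary epithelial markers had at most 9 members and medians from -0.52 to 1.86. In macrophage cluster 02 their median was 1.27, with 1 of 9 rising and 5 adjusted over the list alone, at a sum of 51.1 CPM in BrM and 53.8 CPM in MFP. The unadjusted camera p was 0.0413 there, 0.0264 in CD8 T-like cells and, at its lowest, 0.0124 in cDC2-like cells, where 3 members summed to 296 CPM in BrM and 101 CPM in MFP.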

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

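The comparison with the limit of a count of 0 was chosen after the cluster had been seen. A cluster of 168 cells with epithelial and milk-protein genes (Csn3, Wfdc2, Krt18, Aqp5 and Lcn2 among its leading genes) appeared in all 6 libraries, although the sort took CD45-positive cells, and it was left out of every comparison. It held 8, 68 and 17 cells in BrM 1 to 3 and 17, 18 and 40 cells in MFP 1 to 3. These are 0.109%, 0.951% and 0.223% of the cells of the BrM libraries and 0.229%, 0.228% and 0.650% of the MFP libraries. It is listed here because these shares exceed what a count of 0 would allow, 0.0407%, 0.0420% and 0.0394% in BrM and 0.0404%, 0.0380% and 0.0487% in MFP. Any count above 3 cells would do so, and this is no test of the cells. The injected line is a breast cancer line, but no test of these cells' origin was made. Groups of 3 libraries are too small for a test of outlying samples.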

How the results depend on the processing

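All settings by library kind, with lymphoid or myeloid cells or only named classes as the total, and with all macrophage-like clusters together, were chosen after the data were seen; the others were fixed before. No named gene that was called reversed its direction, but the balance of higher and lower calls moved. Without TMM it was 140 higher and 533 lower in macrophage cluster 02 (388 and 327 with TMM), 13 and 25 in monocyte-like cells (22 and 19) and 0 and 8 in Treg-like cells (1 and 10), and under DESeq2 158 and 94 in Treg-like and 171 and 71 in CD4 cells (0 and 1 in edgeR). Named genes were counted once per class. Of 593 values of the 45 pairs of named gene and class that were called, 386 stayed past the threshold and 207 kept their direction without passing. Of 566 values of the 36 pairs that were not called, 408 stayed uncalled and 158 passed. No called list changed the sign of its median without TMM or under DESeq2 (71 lists, 0 changes). When library kind was a term, 63 of the 71 stayed called with the same sign, 6 kept the sign without a call and 2 turned. Among the libraries of lower total 11 of 58 turned, 4 of them with a call, and among those of higher total 5 of 71, 1 with a call. Examples were proliferation in CD8 cells, from 0.41 to -0.10 with library kind as a term. Within the libraries of lower total the median was -0.12 for interferon-gamma and -0.14 for MHC class I genes in B-like cells, -0.34 for proliferation in NK-like and -0.20 in monocyte-like cells, and within those of higher total 0.68 for inhibitory receptors and 0.23 for residency genes in CD8 cells. Where a count moved by over 1.5 times, the cause was not tested.

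The 0 classes called for shares by edgeR (0 at an unadjusted p under 0.05, exact p of 0.1 or more) stayed at 0 without microglia-like cells in the total, with TMM, with doublets kept, at both other resolutions, with cells classed singly, under the stricter filter, with the replicate block, with named classes only and without each library (0 to 0). They became 12 with library kind as a term, 2 with lymphoid cells as the total, 1 with lymphoid cells and library kind, and 1, cluster 36, with myeloid cells as the total.

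Gene counts under DESeq2 were 40 in NK-like, 242 in CD4, 7 in CD8, 252 in Treg-like, 81 in monocyte-like, 16 in cDC2-like cells and 11 in macrophage cluster 02, against 0, 1, 0, 11, 41, 0 and 715 in edgeR. Without TMM the CD4 count was 6. With only all-zero genes removed, the counts were 10 in NK-like, 260 in CD4, 5 in CD8, 494 in Treg-like, 30 in B-like, 253 in monocyte-like and 66 in cDC2-like cells. Keeping doublets gave 8 in NK-like and 108 in monocyte-like cells and 446 in macrophage cluster 02. Thinning to the smallest library gave 7 in NK-like, 19 in CD4, 260 in Treg-like, 22 in monocyte-like and 1 in cDC2-like cells and 0 in macrophage cluster 02. With cells classed singly, the counts were 1 in NK-like, 2 in CD4, 1 in CD8, 25 in Treg-like, 98 in monocyte-like and 1 in cDC2-like cells. With all macrophage-like clusters together there were 362 genes.

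With library kind as a term the gene counts were 9 in NK-like, 240 in CD4, 7 in Treg-like, 2 in B-like, 408 in monocyte-like and 146 in cDC2-like cells and 1562 in macrophage cluster 02. Within the libraries of lower total they were 731 in NK-like, 1292 in CD4, 961 in CD8, 1 in Treg-like, 50 in B-like and 94 in monocyte-like cells. Within those of higher total they were 394, 1477, 2, 1051, 105 and 1399 in the same order, 100 in cDC2-like cells and 1522 in macrophage cluster 02.

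Without 1 library, gene counts ranged from 0 to 875 in NK-like cells (875 without BrM 1), 0 to 1711 in CD4 (1711 without BrM 1, 5 without BrM 3, 2 without MFP 3, 0 without BrM 2, MFP 1 or MFP 2), 0 to 0 in CD8, 4 to 708 in Treg-like cells (536 without BrM 1, 4 without BrM 2, 6 without BrM 3, 708 without MFP 1, 7 without MFP 2, 4 without MFP 3) and 0 to 374 in B-like cells (374 without BrM 1). They ranged from 1 to 259 in monocyte-like cells (259 without BrM 1, 3 without BrM 2, 1 without BrM 3, 15 without MFP 1, 9 without MFP 2, 22 without MFP 3), 0 to 25 in cDC2-like cells (25 without BrM 1) and 10 to 1522 in macrophage cluster 02 (25 without BrM 2, 10 without BrM 3, 1522 without MFP 1).

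Called lists fell to 0 in every class with an estimated correlation. By fry they fell to 1 in CD4 and 0 in NK-like, CD8, Treg-like, B-like, monocyte-like and cDC2-like cells and macrophage cluster 02. With library kind as a term there were 8 in NK-like and 7 in cDC2-like cells. Within the libraries of lower total there were 13 in NK-like, 12 in CD8 and 1 in B-like cells, and within those of higher total 8 in NK-like and 11 in cDC2-like cells. Without 1 library, lists ranged from 5 to 9 in NK-like (8 without BrM 1, 9 without MFP 3), 9 to 10 in CD4, 4 to 10 in CD8 (10 without BrM 2), 11 to 12 in Treg-like, 2 to 7 in B-like (2 without BrM 3), 9 to 16 in monocyte-like (9 without BrM 3) and 3 to 6 in cDC2-like cells and 9 to 12 in macrophage cluster 02.

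Libraries with the same replicate number deviated together only in part. The correlation of the 2 libraries numbered 3, both of higher total, was positive in every class (0.0065 to 0.492), and that of the 2 numbered 2, one of each kind, ran from -0.561 to 0.0466. All such correlations ran from -0.561 to 0.544 over 21 pairs in 7 classes, 9 were over 0.1, and 7 of the 21 were highest with their own number, so the numbers were not taken to pair the libraries. The replicate number as a block moved the gene counts to 4 in CD4, 2 in CD8, 11 in B-like, 87 in monocyte-like and 76 in cDC2-like cells, and the lists to 8 in NK-like and 8 in cDC2-like cells. It changed no other count by over 1.5 times.

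Not run were cells classed singly and the replicate block in macrophage cluster 02, cDC2-like cells without MFP 2, the libraries of lower total alone in cDC2-like cells and macrophage cluster 02, and tests of neutrophil-like, cDC1-like and mature DC-like cells, which had too few libraries with 20 cells. Gamma-delta T-like cells and macrophage cluster 28 had enough, but no gene test was made of them. For the Fcer1g-high T clusters the leave-one-out, block, thinning and doublet settings are not given. The smallest libraries tested held 180078 UMIs in B-like cells, 195267 in macrophage cluster 02 and 312434 in monocyte-like cells.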

Other observations

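The tests by library kind, of the CD11b gate, of heat shock genes and of other splits were chosen only after the results were seen; those of sequencing depth and free RNA were fixed before their result was known. A group of T cell clusters with high Fcer1g, an adaptor gene otherwise typical of NK and myeloid cells, was left without a class name. Its largest cluster, 03, had Klra6, Nsg2, Ikzf2 and Lef1 among its leading genes. Cluster 08 had Klra6, Tcrg-C2, Cd160, Gzmb and Gzmc, the last 2 genes of killing granules. Cluster 22 was led by interferon genes such as Ifit1, and cluster 33 had Tcrg-C4 and Tcrg-C2. The group made up 10.8%, 8.04% and 10.5% of cells in BrM 1 to 3 and 16.1%, 18.1% and 9.87% in MFP 1 to 3 (exact permutation p = 0.3). In 2159 BrM and 3223 MFP cells, interferon response genes had a median log2 fold change of 0.21, with 2 of 25 rising adjusted over the list alone (camera adjusted p = 1.80e-06; adjusted p = 0.656 with an estimated correlation). The interferon-gamma list had 1 of 21 rising adjusted over the list alone (camera adjusted p = 0.00511; adjusted p = 0.748 with an estimated correlation). The proliferation list had a median of 0.26 (25 measured, adjusted p = 0.928 with an estimated correlation), the TGF-beta list one of -0.20 (12 measured, adjusted p = 0.748 with an estimated correlation) and the residency list one of -0.22 (16 measured, adjusted p = 0.656 with an estimated correlation), each at a camera adjusted p = 0.0188. The proliferation median turned to -0.24 with library kind as a term, and was -0.43 within the libraries of lower total and -0.03 within the others. Adjusted over the list alone, 1 TGF-beta gene fell. Single genes, chosen after their values were seen, were granzyme Gzma at -1.85 (SE 0.30), Itgae at -0.94 and the interferon-induced Ifi204 at 1.43 (SE 0.27), none passing. In edgeR 0 of 10565 genes passed, with 817 at an unadjusted p under 0.05 and 25 in DESeq2.

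A cluster led by Il1rl1, Il5, Il13, Areg and Calca, genes of type 2 immunity, was set among T cells by its CD3 genes (100 CPM or more). Those 5 genes are markers of the ILC2-like class (group 2 innate lymphoid cells), so innate lymphoid cells were not excluded. The cluster held 29, 8 and 7 cells in BrM 1 to 3 and 161, 486 and 6 cells in MFP 1 to 3. Of lymphoid cells these are 0.409%, 0.259% and 0.190% against 2.24%, 6.23% and 0.326%, and with lymphoid cells as the total the difference passed the edgeR test (log2 fold change -3.34, SE 0.84). It did not pass with library kind as a further term (-2.35, SE 0.88). Several myeloid clusters lay mostly in 1 library or site. Cluster 30, led by Folr2, Mrc1, Lyve1 and Cd209f, genes of connective tissue macrophages, was 5.21% of MFP 3 and 0%, 0.198% and 0.105% of BrM 1 to 3. Cluster 36, led by Retnla, Lyz1, Fn1 and Ear2, was 1.93% of MFP 3, with 1 cell in MFP 2 and 0 in the other libraries. Cluster 25, led by Mmp12, Mmp13 and Arg1, was 6.49% of MFP 3 and 1.399% and 1.41% of BrM 2 and BrM 3. Cluster 16 was 6.55% and 6.36% of BrM 2 and BrM 3 and 0.588% of MFP 3. Cluster 27, with a low median depth and Inhba and Hcar2 in the lead, was 7.44% of MFP 3 and under 0.4% of each other library. A cluster mostly of MFP 3 cannot be told apart from a property of that library, since the other MFP libraries held few myeloid cells.

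BrM 1, MFP 1 and MFP 2 held few myeloid cells (3.69%, 2.82% and 0.965% of classified cells, against 51.6% to 69.9% in the others). Lower sequencing depth is argued against, because 0.583% of the 12186 myeloid cells of the other libraries (median 9215 UMIs) would drop below 500 UMIs at the ratio of library totals (0.774). A gate that left out CD11b-bearing cells is argued against as the whole cause. Plasmacytoid DC-like cells, whose Itgam level (5.64 CPM) was below that of NK-like cells (82.7 CPM), were at 0.254 per 100 lymphoid cells in BrM 1 against 5.48 and 3.04 in BrM 2 and BrM 3, and at 0.0973 and 0 in MFP 1 and MFP 2 against 1.57 in MFP 3, ratios of 0.0595 and 0.0309. The submitters' library numbers separate the same 3 libraries, so the 2 kinds may also be separate sorting or sequencing runs. Such runs, a gate on another property, a loss of cells before loading and a difference between tumours may each account for it and were not tested.

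The interferon response list was called higher in BrM in 6 named classes (adjusted p = 0.179 or more with an estimated correlation, so no call held there), but not called in Treg-like cells, nor in macrophage cluster 02 with all its libraries and no term for library kind. Uneven library kinds are argued against as the whole cause, because the mean over 7 classes of the list's median log2 fold change was 0.379 without and 0.347 (SE 0.055) with library kind in the model; the classes share their libraries, so these values are not independent. Free RNA from myeloid cells is argued against as the source of the excess CPM summed over the list in NK-like, CD4 and CD8 cells. It could bring at most 0.217, 0.0240 and 0.0503 times that excess in BrM. The sum does not decide for the list call, which does not weigh members by level, or for members of low level. In NK-like cells the largest estimated free share was 2.97%, while Rsad2 and Ifit3 lay at 0.0189 and 0.0316 times their highest level in another class. A difference between the sites stays open as a hypothesis, as do differences in handling that follow the site. In 10 splits of the 6 libraries, 53 lists were called for the sites and at most 51 for another split, BrM 1 with MFP 2 and MFP 3; only 1 of the 10, the split by site itself, reached 53, and 10 splits are too few for a share under 0.05.

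Immediate-early genes such as Fos and Fosb were lower in BrM; Fos fell in Treg-like cells and Fosb in Treg-like, CD4 and monocyte-like cells. These transcripts are induced by signalling in tissue and also by tissue digestion. A stress response that moves heat shock and immediate-early genes the same way is argued against by the direction of change only. The 7 heat shock members of the list had a mean median log2 fold change of 0.213 (SE 0.0617) over 9 classes, above 0 in 8 of them. The 13 immediate-early members had one of -0.332 (SE 0.0729), below 0 in 9 of 9. The classes share their libraries, so the SEs do not measure the spread between libraries and the counts of classes are not independent. A handling response without heat shock genes or with opposite moves, such as a different time to digestion, was not tested. Less signalling in the cells of the brain tumours was not tested either, and each may account for the difference.

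Other splits of the 6 libraries point to a structure that is not the site, library kind, which was itself defined after the data were seen. The split by library kind called 825 genes in NK-like, 232 in CD4, 252 in CD8, 13 in Treg-like, 65 in B-like, 172 in monocyte-like and 1369 in Fcer1g-high T cells, in each case the highest of the other splits, against the 0, 1, 0, 11, 0, 41 and 0 of the sites. Counting the split by site itself, as many genes were reached by 10 of 10 splits in NK-like, CD8, B-like and Fcer1g-high T cells. That was certain, because the sites gave 0 genes there. In CD4, Treg-like and monocyte-like cells 2 of 10 splits reached as many. For shares, the split by library kind called 14 classes against 0 for the sites. It sets the lymphoid-rich libraries against the others, so many calls follow from how it was chosen. That 10 of 10 splits reached as many classes as the sites was again certain with 0 calls. With 10 splits no share can be under 0.05. With library kind in the model the site calls were 9, 240, 0, 7, 2, 408 and 481 genes in the same order, and 12 classes.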
